A study of Homo sapiens with 6 samples.

How the data were processed

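The series measured polyadenylated RNA in 6 libraries of the THP1 line, labelled shCtrl, shALKBH5 and ALKBH5 rescue with 2 replicates each. The deposited tables give an estimated count, a TPM value, a length and an effective length for each of 179973 Ensembl transcripts. Per the submitters' processing notes, CASAVA and kallisto 0.43.1 were used, with the build hg38. The files' columns are those of a kallisto abundance table. The options of the quantification are not given in the sources used here. Per the labels' protocols, libraries were made from oligo-dT selected RNA with random priming and PCR. No molecular identifiers are mentioned, and strand use in the quantification is not given in the sources used here. kallisto divides reads that fit several transcripts by an iterative estimate, so genes with near-identical copies have uncertain counts.

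The authors' estimated counts were summed per gene with the GENCODE release 29 annotation (GRCh38), which matched 163714 transcripts (91.0%) without regard to ID versions. The 16259 unmatched transcripts held 3.13% to 3.32% of the estimated counts per library and were left out of library sizes and tests. They include copies on alternative haplotypes, so HLA genes are counted only in part. The transcript set had no match for MALAT1, NEAT1 and 4 other nuclear-retained RNAs, so the list of 6 such RNAs was not tested. Sums were rounded to whole numbers. Gene coordinates are those of GENCODE. The deposited TPM values were used only to describe the transcripts of ALKBH5. Total estimated counts ran from 14534386 to 24857373 per library.

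Samples were grouped by title. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest, all 6 libraries, 1 coefficient per group, 3 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05 over 14497 genes. A standard error is the absolute log2 fold change divided by the square root of the F statistic, and 95% intervals use its t distribution. CPM values are counts scaled by the TMM-adjusted library size. Gene lists, fixed before the data were examined, were tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at a preset correlation of 0.01 between genes. An estimated correlation and fry were run beside it, with adjustment over the 38 lists that had at least 3 tested members. camera compares a list with the other genes, while fry asks whether its members move one way.

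Replicate numbers come from the sample titles, and no label states a shared day or batch. The correlation of deviations from the group means was 0.60 to 0.73 for the 6 pairs of same-numbered libraries. With 2 libraries per group the deviations of numbers 1 and 2 mirror each other, so these are 3 separate values. The first principal component separated the numbers. The numbers were therefore treated as pairing the libraries, a decision made before the calls of both fits were compared, and a fit with replicate number as a block (2 residual degrees of freedom) is given where it changes a call. The biological coefficient of variation was 27.7% without the block and 10.6% with it. The chi-square statistic per gene was 3.31 to 16.4 between same-numbered libraries, above sampling noise, so no library was treated as deposited more than once. No sample was assigned to a condition from its values.

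Genes named in the text were chosen by a rule fixed before the data were examined. It takes ALKBH5, the members of 3 short lists, and for each comparison up to 10 protein-coding genes per direction past the threshold with a mean of at least 5 CPM and no overlap between groups. Where fewer than 5 passed, those with the smallest p filled the direction to 5. For each list described, up to 4 members were named by p. The same rule was applied to the coefficient of replicate number, which was added after the data were seen. RPL21P16 was named outside the rule.

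For shALKBH5 against shCtrl, the procedure was tested on simulated data with the means, library sizes, replicate-number differences and dispersions of the real libraries. Among 14497 genes, 200 with a mean of at least 1 CPM were changed in shALKBH5. Of those changed 2-fold, 82% were recovered with the block and 0% without it, and of those changed 4-fold, 97% and 0%. With the block, 12 unchanged genes were called, and without it 0. For replicate number 2 against 1, 91% and 100% were recovered, with 31 unchanged genes called. The comparison without the block therefore had little power for changes of these sizes. Another 20 simulations of unchanged groups gave the expected correlation between comparisons that share libraries, and 20 more that between comparisons made within different replicate numbers, which share none. All simulations drew each gene independently, so shifts shared by many genes of a library are absent from them.

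Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter or a filter of at least 1 CPM in at least 2 libraries, transcript length offsets, a fit of 2 groups only, protein-coding genes only, a minimum change of 1.5-fold, the replicate block, and leaving out each library in turn.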

Results

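Polyadenylated RNA was sequenced from THP1, a human monocytic cell line established from acute myeloid leukaemia that carries an MLL fusion. The study addressed ALKBH5, an enzyme that removes the N6-methyladenosine (m6A) mark from RNA. The 6 libraries fall into 3 labelled groups with n = 2 each. These are a hairpin control (shCtrl), a hairpin knock-down of ALKBH5 (shALKBH5) and the knock-down with ALKBH5 restored (ALKBH5 rescue). The design asks which transcripts change when ALKBH5 is lost and which return when it is put back. Estimated counts totalled 14534386 and 19477197 in shCtrl replicates 1 and 2, 18330205 and 19010128 in shALKBH5, and 24857373 and 16150754 in ALKBH5 rescue. The replicates are those of the sample titles. Levels below are given in CPM, the count scaled by library size. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. In the fit without a block for replicate number, that spread includes the replicate-number difference described below.

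The targeted gene did not follow the group labels. ALKBH5 (ENSG00000091542.8, GRCh38 chromosome 17, 18183078 to 18209954, plus strand) stood at 14.6 CPM in the library labelled shCtrl replicate 1, at 12.4 CPM in that labelled shALKBH5 replicate 1 and at 13.6 CPM in that labelled ALKBH5 rescue replicate 1. In the libraries numbered 2 it stood at 1097, 1003 and 968 CPM in the same order. These levels rest on 202 to 312 estimated counts in the libraries numbered 1 and on 15733 to 20608 in those numbered 2. The main protein-coding transcript held 277 of 312 counts in the library labelled ALKBH5 rescue replicate 1 and 20605 of 20608 in that labelled shCtrl replicate 2. It was at 6.34 and 517 TPM in the libraries labelled shCtrl replicates 1 and 2. The log2 fold change of shALKBH5 against shCtrl was -0.13 (SE 2.48, n = 2 per group) and that of ALKBH5 rescue against shALKBH5 was -0.05 (SE 2.48), with edgeR adjusted p = 1 for both. With replicate number as a block the values were -0.17 (SE 0.11, 95% interval -0.42 to 0.08) and 0.02 (SE 0.11, 95% interval -0.23 to 0.26). Neither the knock-down nor its restoration was therefore detected along the labels. Every direction given below is that of the libraries as labelled.

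**Figure D1:**
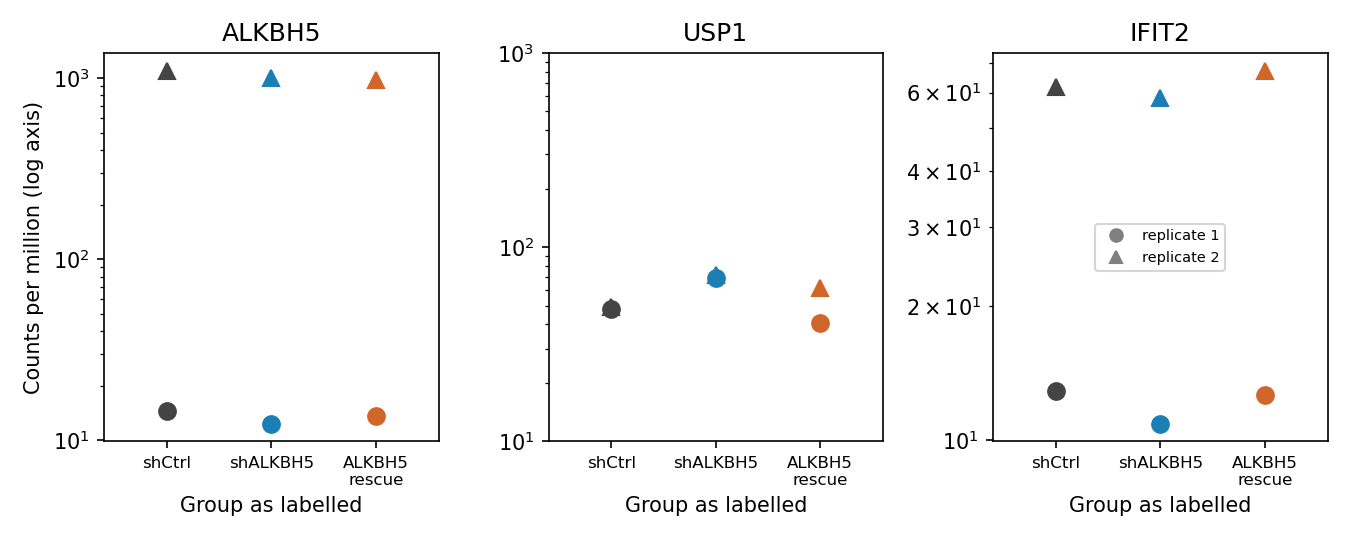
Levels of ALKBH5, of the deubiquitinase gene USP1 and of the interferon-stimulated gene IFIT2 in each library, in CPM on log axes, by labelled group (n = 2), with circles for replicate 1 and triangles for replicate 2. ALKBH5 lies between 12.4 and 14.6 in the libraries numbered 1 and between 968 and 1097 in those numbered 2, and IFIT2 separates by the same number, while USP1 lies between 40.5 and 71.6 in all 6 libraries.

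The transcriptomes as a whole followed the replicate number as well. The first principal component held 65.3% of the variance and placed the libraries numbered 1 between -39 and -32.3 and those numbered 2 between 28.1 and 40.4. Correlations of log2 CPM across genes were 0.987 to 0.992 between libraries of the same number and different groups. Between the 2 libraries of one group they were 0.962 to 0.971. SPP1, which encodes the secreted phosphoprotein osteopontin, was measured at 245 ± 16.5 CPM (SD, n = 3) in the libraries numbered 1 and at 28.0 ± 2.93 CPM (SD, n = 3) in those numbered 2. The interferon-stimulated gene IFIT2 was measured at 12.1 ± 1.05 and 62.5 ± 4.38 CPM (SD, n = 3 each). In a fit with group and replicate number, edgeR's quasi-likelihood test called 6585 of 14497 genes between the numbers, 3303 higher and 3282 lower in number 2. Without the library labelled shALKBH5 replicate 1 it called 3915 genes, and without that labelled shALKBH5 replicate 2 it called 4030. The groups are crossed with the numbers, so each comparison below can be made within a number.

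**Figure D2:**
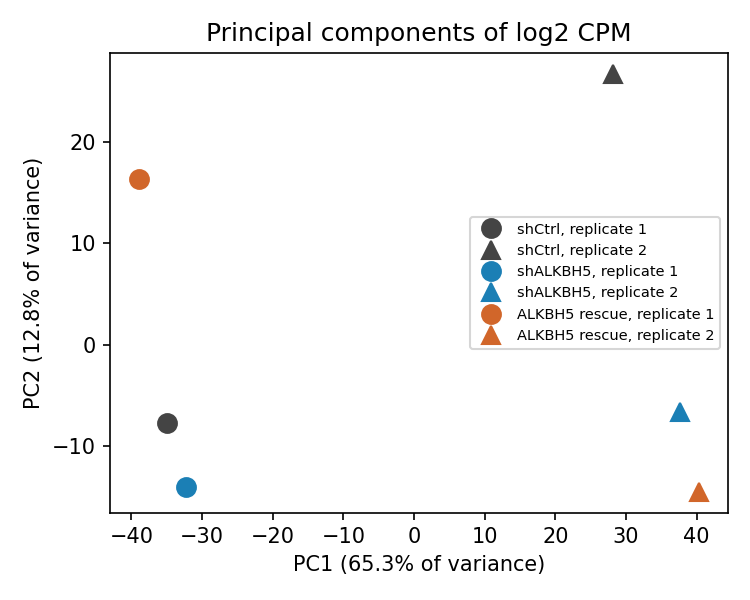
First and second principal components of log2 CPM (65.3% and 12.8% of the variance) for the 6 libraries, with colours for the labelled group and circles or triangles for replicate 1 or 2. The libraries separate along the first component by replicate number, from -39 to -32.3 for number 1 and from 28.1 to 40.4 for number 2, and the 2 libraries of each group lie on opposite sides.

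The first comparison asks what differs between the libraries labelled shALKBH5 and shCtrl. Cytosolic ribosomal protein genes lay lower as a set in the libraries labelled shALKBH5. Their median log2 fold change was -0.10 over 75 genes, of which 4 had a positive value (camera adjusted p = 0.0152, and adjusted p = 0.991 with an estimated correlation). None of the 75 passed alone, and the members with the smallest p did not share a direction. RPS24 was at -0.24 (SE 0.17), RPS3A at -0.23 (SE 0.18) and RPL26 at -0.25 (SE 0.23), while RPL21 was at 0.79 (SE 0.44). Within replicate number 1 the median of the list was -0.05 and within number 2 it was -0.16. With replicate number as a block, nuclear genes of oxidative phosphorylation were also called lower (median -0.11, camera adjusted p = 0.0236, and adjusted p = 0.95 with an estimated correlation). Their adjusted p was 0.0708 without the block. In that fit without the block NDUFB3, a complex I subunit, was at -0.29 (SE 0.18), NDUFA1 at -0.21 (SE 0.21) and COX7B, a subunit of cytochrome c oxidase, at -0.17 (SE 0.20). Leaving out 1 library changed the number of lists called. Without the block, a group left with 1 library carries the replicate-number difference, so this change cannot be read as one along the labels.

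No single gene passed between these groups. edgeR called 0 of 14497 genes, with 38 at an unadjusted p under 0.05 where 725 would be expected by chance, and DESeq2 and limma-voom also called 0. None of these fits had the block. In simulated data the edgeR fit without it recovered 0% of 2-fold and 0% of 4-fold changes, so these calls of 0 set little limit. The genes named next are those with the smallest p among genes that met the naming rule, not among all genes. That rule asks for protein-coding genes with a mean of at least 5 CPM and no overlap between groups, so separated values were required. On the higher side these were MTRNR2L12, LYSMD3, FCF1, MT-ATP8 and USP1. LYSMD3 was at 6.58 and 6.60 CPM in the libraries labelled shCtrl and at 10.7 and 11.4 CPM in those labelled shALKBH5, a log2 fold change of 0.75 (SE 0.30, edgeR adjusted p = 1). FCF1, a factor in small-subunit ribosomal RNA processing, had a log2 fold change of 0.81 (SE 0.36). MT-ATP8, a mitochondrially encoded subunit of ATP synthase, was at 0.46 (SE 0.21). USP1, a deubiquitinase of the Fanconi anaemia pathway linked to ALKBH5 in other work, was at 48.1 and 48.9 against 68.9 and 71.6 CPM, a log2 fold change of 0.54 (SE 0.24). Its difference was 0.52 within number 1 and 0.55 within number 2. USP1 was the 1 member of its list of 6 tested genes that passed when adjusted over the list alone with the block, and 0 passed without it. It was the only such call in this comparison over the 38 lists, each adjusted separately, so chance is not excluded. MTRNR2L12 was at 0.54 (SE 0.21) and shares sequence with mitochondrial ribosomal RNA, so its counts are uncertain. On the lower side stood ALKBH3, a relative of ALKBH5 that repairs alkylated nucleic acids, at -0.41 (SE 0.22), TARSL2 at -0.45 (SE 0.25), ANKRD9 at -0.35 (SE 0.20), INPP5K at -0.36 (SE 0.21) and KCTD21 at -0.42 (SE 0.25). All of these had an edgeR adjusted p of 1.

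With the block, 347 genes had an unadjusted p under 0.05 and 1 gene passed, the processed pseudogene RPL21P16 (chromosome 10, 120354701 to 120355183), named after its value was seen. It was at 0 counts in both libraries labelled shCtrl and in every library numbered 1. It was at 14.4 CPM in the library labelled shALKBH5 replicate 2 and at 14.9 CPM in that labelled ALKBH5 rescue replicate 2. Against a floor of 3 counts over the shCtrl group, its mean was at least 78.5-fold higher in shALKBH5 (edgeR adjusted p = 0.0104 with the block) and at least 80.9-fold higher in ALKBH5 rescue (adjusted p = 0.01). Each of these means and calls rests on 1 library, numbered 2, against 1 of the same number at 0, since all 3 libraries numbered 1 are at 0. The pseudogene shares nearly all its sequence with RPL21, so its counts are uncertain. No molecular identifiers are mentioned for the reads, so floors and count-based intervals are taken to cover counting error only. With the block, DESeq2 called 1 gene and limma-voom 0 between shALKBH5 and shCtrl.

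The second comparison asks what differs between the libraries labelled ALKBH5 rescue and shALKBH5. Cytosolic ribosomal protein genes and nuclear oxidative phosphorylation genes lay higher as sets in the libraries labelled ALKBH5 rescue, with medians of 0.11 and 0.12. A positive value was found for 69 of 75 and 33 of 36 members (camera adjusted p = 0.00548 for each, and adjusted p = 0.965 with an estimated correlation). No member passed alone. With the block, RPS24 was at 0.29 (SE 0.13), RPS27A at 0.27 (SE 0.11), NDUFB3 at 0.25 (SE 0.13) and COX7B at 0.23 (SE 0.12). The direction did not hold within both numbers. The medians were 0.23 and 0.23 within number 1 for the ribosomal and oxidative phosphorylation lists, and -0.08 and -0.02 within number 2. The number of lists called also changed when 1 library of either group was left out, but those fits bring in the replicate-number difference. Both comparisons share the libraries labelled shALKBH5, so opposite directions arise in part by construction.

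edgeR called 0 of 14497 genes between ALKBH5 rescue and shALKBH5, with 43 at an unadjusted p under 0.05 and 290 with the block, and DESeq2 and limma-voom called 0 with and without it. Among genes that met the naming rule, those with the smallest p on the higher side included PPEF2, a protein phosphatase gene, at 1.10 (SE 0.42). The others were FAM156B at 0.97 (SE 0.36), AMACR, a racemase of branched-chain fatty acid breakdown, at 0.56 (SE 0.27), SULT1A3 at 0.54 (SE 0.24) and CCDC125 at 0.49 (SE 0.26). FAM156B and SULT1A3 each have a near-identical copy, so their counts are uncertain. On the lower side stood GLIS2, a zinc-finger transcription factor gene, at -0.88 (SE 0.36), ZNF92 at -0.84 (SE 0.31), MT-ATP8 at -0.65 (SE 0.21), PYROXD1 at -0.65 (SE 0.23) and ZNF117 at -0.52 (SE 0.23). The edgeR adjusted p was 1 for each. MT-ATP8 was at 73.9 and 62.5 CPM in the libraries labelled shALKBH5 and at 43.7 and 42.9 CPM in those labelled ALKBH5 rescue. It was the 1 member of 13 mitochondrially encoded genes that passed when adjusted over the list alone with the block, and 0 passed without it. No other member of the 38 lists, each adjusted separately, passed in this way in this comparison, so chance is not excluded.

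The third comparison sets the libraries labelled ALKBH5 rescue against those labelled shCtrl. None of the 38 gene lists tested stood apart (lowest camera adjusted p = 0.923). Ribosomal protein genes had a median of 0.18 within number 1 and of -0.23 within number 2. Lists were called when 1 library of either group was left out, but those fits bring in the replicate-number difference. edgeR called 0 of 14497 genes, with 46 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. With the block, edgeR called RPL21P16 alone, DESeq2 and limma-voom called 0, and 239 genes had an unadjusted p under 0.05. Genes were again named by the smallest p among those that met the naming rule. Highest of them were PPEF2 at 1.24 (SE 0.42), FAM156B at 0.76 (SE 0.36), JRKL at 0.63 (SE 0.31), ZNF468 at 0.62 (SE 0.33) and NAP1L5 at 0.61 (SE 0.30). Lowest were SMN1 at -1.57 (SE 0.76), GLIS2 at -0.73 (SE 0.36), ARMC10 at -0.66 (SE 0.28), DOHH, an enzyme of hypusine synthesis, at -0.66 (SE 0.34) and CEBPD, a myeloid transcription factor gene, at -0.55 (SE 0.28). None passed (edgeR adjusted p = 1 for each). SMN1 has a near-identical copy, and its counts are uncertain. PPEF2 lay at 3.33 and 2.29 CPM in shCtrl and at 4.78 and 8.49 CPM in ALKBH5 rescue.

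The receptor gene AXL, known from the study as part of its axis and probably chosen on these samples, had low counts, with 7 to 34 estimated counts per library. It was at 0.506 and 1.44 CPM in the libraries labelled shCtrl, 0.914 and 1.68 CPM in those labelled shALKBH5 and 0.652 and 2.09 CPM in those labelled ALKBH5 rescue. Its log2 fold change was 0.39 (SE 0.76) in shALKBH5 against shCtrl and 0.05 (SE 0.75) in ALKBH5 rescue against shALKBH5 (edgeR adjusted p = 1). With the block the first was 0.46 (95% interval -0.42 to 1.34), so no difference of AXL was found along the labels, while a 2-fold difference is not excluded. Without the library labelled shCtrl replicate 1 the first value was -0.14, and without that labelled ALKBH5 rescue replicate 2 the second was -1.0. These 2 fits had no block and left 1 library in a group, so they bring in the replicate-number difference. Within numbers 1 and 2 the first comparison gave 0.85 and 0.23, and the second -0.49 and 0.32. Of the other receptors and ligands of the AXL family, MERTK was at 0.14 (SE 0.22), TYRO3 at -0.22 (SE 0.58), GAS6 at -0.04 (SE 0.39) and PROS1 at 0.11 (SE 0.51) in shALKBH5 against shCtrl. These errors include the replicate-number difference. With the block the values were 0.14 (SE 0.16), -0.20 (SE 0.14), -0.06 (SE 0.10) and 0.09 (SE 0.15) in the same order. Their 95% intervals with the block lay between -0.53 and 0.49. KDM4C, a histone demethylase gene of the study's axis, was at -0.03 (SE 0.18), MYB at -0.04 (SE 0.15) and POLR2A at 0.02 (SE 0.21).

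None of the genes linked to ALKBH5 in other work passed either. MYC was at -0.03 (SE 0.34), FOXM1 at -0.17 (SE 0.25), TACC3 at -0.08 (SE 0.16), PER1 at 0.06 (SE 0.26) and NANOG, at under 1 CPM in every library, at -0.85 (SE 0.53) in shALKBH5 against shCtrl. With the block the values were -0.03 (SE 0.11), -0.16 (SE 0.11), -0.08 (SE 0.10), 0.07 (SE 0.14) and -0.87 (SE 0.53) in the same order. WIF1 had 0 estimated counts in all 6 libraries. The 9 genes of the m6A methyltransferases and their complex partners had a median of -0.03 and the 10 tested demethylase and reader genes a median of -0.05 (camera adjusted p = 0.992 and 0.805). In none of the 3 comparisons did a member of the 38 lists pass, over all genes or when adjusted over the list alone, in the fit without the block. Markers of other blood and tissue cell types were mostly untested for low counts. Of 13 T and NK cell genes 3 were tested, of 8 B cell genes 4, of 13 erythroid and megakaryocyte genes 2, and of 12 epithelial and fibroblast genes 4. The highest of them was IL7R at 27.4 ± 2.11 CPM (SD, n = 6).

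The reversal that the rescue tests for was measured across genes. edgeR called 0 genes in each of both comparisons (38 and 43 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom), so an overlap of calls could not be examined. Log2 fold changes of both comparisons correlated across 14497 genes at r = -0.461, and genes are not independent replicates. Unchanged groups simulated around the same shared shALKBH5 libraries gave r = -0.491 on average (SD 0.012). The covariance was -0.0474 against a simulated -0.0366 (SD 0.0014), a difference of -0.0108. Without the library labelled shALKBH5 replicate 1 or 2, r was -0.766 and -0.734. With 1 shALKBH5 library left and no block, both comparisons carry the replicate-number difference with opposite signs. A strongly negative r then arises by construction and does not measure a reversal. The value of r was -0.297 without the library labelled shCtrl replicate 1 and -0.202 without that labelled ALKBH5 rescue replicate 1. In these fits only 1 of the comparisons carries the replicate-number difference. Taking each comparison within a different replicate number leaves no library in both. With shALKBH5 against shCtrl within number 1 and ALKBH5 rescue against shALKBH5 within number 2, r was -0.011, within the range of -0.026 to 0.035 in 20 simulations of unchanged groups. With the numbers exchanged r was -0.243, outside the simulated range of -0.028 to 0.022. The simulations drew each gene independently, so their spreads leave out shifts shared by many genes of a library. In the 2 comparisons of this split, ribosomal protein genes had medians of -0.16 and 0.23. A value outside the simulated range therefore cannot be told from such shifts between single libraries. The negative correlation was thus not shared by both splits.

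**Figure D3:**
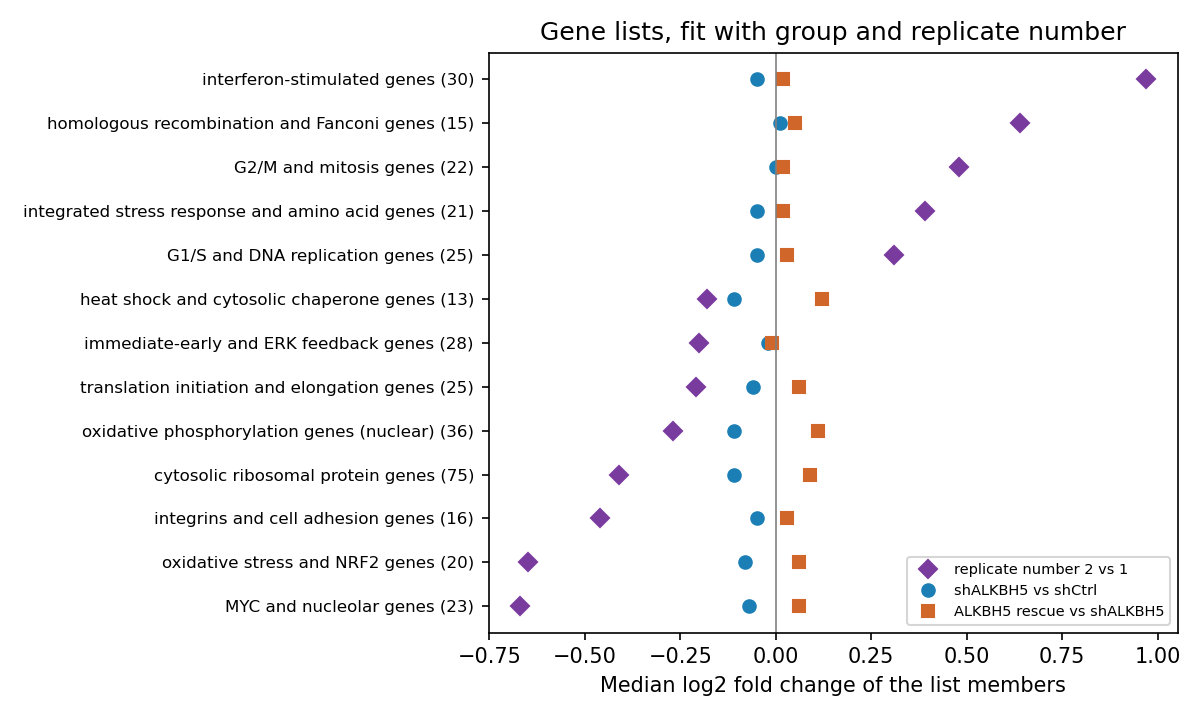
Median log2 fold change of the members of 13 gene lists (number of tested genes in brackets) in the fit with group and replicate number. Diamonds give replicate number 2 against 1, circles shALKBH5 against shCtrl and squares ALKBH5 rescue against shALKBH5. The lists shown are those called by camera between the numbers (none of them with an estimated correlation, adjusted p = 0.562 to 0.837), where medians run from -0.67 for MYC and nucleolar genes to 0.97 for interferon-stimulated genes, and circles and squares lie near 0.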

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

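Chosen only after the data were seen were the tests of replicate number, the correlation with no shared library and the fits that combine the replicate block with RLE, DESeq2 or limma-voom. The 3 counts of changed genes stayed at 0 in every alternative without the replicate block, leave-one-out fits included. With the replicate block 1 gene was called in shALKBH5 against shCtrl and 1 in ALKBH5 rescue against shCtrl. With RLE and the block the counts were 1 and 1, and with DESeq2 and the block 1 gene was called in shALKBH5 against shCtrl. Adjusted over the list alone, the block added 1 gene in shALKBH5 against shCtrl (USP1) and 1 in ALKBH5 rescue against shALKBH5 (MT-ATP8), and camera called 2 lists in place of 1 in the former. Each of the 38 lists was adjusted separately, so these 2 genes may be calls by chance. The block removes the replicate-number difference from the spread, by construction. With no calls in one or both comparisons, the number of genes called and called back was fixed at 0. In simulated data the fit without the block recovered 0% of 2-fold and 0% of 4-fold changes, so its 0 calls set little limit. These simulations were of shALKBH5 against shCtrl and changed only genes with a mean of at least 1 CPM. There the fit with the block recovered 82% and 97%. Its count of 1 speaks against many such changes in that comparison only if the real libraries vary like the simulated ones. In the real data this fit gave 347 genes at an unadjusted p under 0.05 where 725 would be expected by chance, so real recovery may be lower. Recovery in the other labelled comparisons was not simulated.

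List calls ended with an estimated correlation and with fry in either form (0 lists in place of 1 in shALKBH5 against shCtrl, and 0 in place of 2 in ALKBH5 rescue against shALKBH5). Leaving out 1 library gave 2 to 8 lists in each of these comparisons and 0 to 8 in ALKBH5 rescue against shCtrl (the cause was not tested). In all leave-one-out fits the lone library is assumed to vary like the other groups. The correlation of fold changes was -0.500 without a filter and -0.421 with the CPM filter, and ran from -0.766 to -0.202 without 1 library. That range follows in part from the design, since a group left with 1 library carries the replicate-number difference. With no shared library it was -0.011 and -0.243. Between replicate numbers, 1044 genes passed at a minimum change of 1.5-fold, and 3915 to 6811 without 1 library. Of the 6585 genes, 4771 were also called by DESeq2 and 6518 by limma-voom in the same direction. HIST2H2AA3 no longer passed with DESeq2.

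Directions turned for 77 values of 26 named results, and none of the turned values passed the threshold. Their main values reached at most 0.39 on the log2 scale. Without 1 library, ALKBH5 ran from -5.49 to 5.13 in shALKBH5 against shCtrl and from -5.24 to 5.31 in ALKBH5 rescue against shALKBH5, because 1 replicate number then dominates a group. In the same order of comparisons AXL ran from -0.14 to 1.36 and -1.0 to 0.68, KDM4C from -0.15 to 0.10 and -0.04 to 0.12, POLR2A from -0.21 to 0.21 and -0.33 to 0.10, and MERTK from -0.01 to 0.31 and -0.05 to 0.04. TYRO3 ran from -0.92 to 0.55 and -0.53 to 0.69, GAS6 from -0.48 to 0.29 and -0.42 to 0.45, PROS1 from -0.38 to 0.51 and -0.71 to 0.56, TACC3 from -0.17 to 0.02 and -0.03 to 0.14, and FOXM1 from -0.42 to 0.14 and -0.10 to 0.28. PER1 ran from -0.11 to 0.26 and -0.28 to 0.22, and MYC from -0.30 to 0.24 and -0.35 to 0.40. MYB ran from -0.10 to 0.02 in the first comparison and NANOG from -0.09 to 0.69 in the second. With the replicate block, ALKBH5 was at 0.02, AXL at 0.00 and TYRO3 at 0.04 in ALKBH5 rescue against shALKBH5. With RLE and the block, ALKBH5 was at 0.03, MERTK at 0.01 and TYRO3 at 0.05. With DESeq2 and the block, ALKBH5 was at 0.03, AXL at -0.06, MERTK at 0.01 and TYRO3 at 0.05, and with limma-voom and the block MERTK was at 0.00 and TYRO3 at 0.03. Without the block, limma-voom gave -0.17 for AXL, -0.04 for PROS1 and 0.01 for TYRO3. RLE and DESeq2 each gave 0.01 for MERTK, TYRO3 and PER1, and no filter gave 0.00, 0.00 and 0.01. Length offsets gave 0.06 for MERTK, 0.02 for TYRO3, 0.34 for PER1 and -0.02 for MYC in that comparison, and 0.02 for MYB, 0.06 for TYRO3, -0.11 for PER1 and 0.02 for MYC in shALKBH5 against shCtrl. As for ALKBH5, a group left with 1 library holds 1 replicate number, so part of the replicate-number difference enters the other leave-one-out ranges too. How much of each range this makes up was not examined. The cause was not tested for values that turned under the other settings. Counts were low for AXL, at 7 to 34 estimated counts per library, and for NANOG, at under 1 CPM. Genes named by p in the labelled comparisons kept their direction without 1 library, but many sizes moved. The kept direction is no support, since the naming rule required groups without overlap and so largely fixed it in advance. In shALKBH5 against shCtrl ALKBH3 ran from -0.58 to -0.21 and KCTD21 from -0.63 to -0.23, but LYSMD3 only from 0.69 to 0.80. In ALKBH5 rescue against shALKBH5 PPEF2 ran from 0.62 to 1.46, CCDC125 from 0.28 to 0.73 and GLIS2 from -1.24 to -0.40. In ALKBH5 rescue against shCtrl JRKL ran from 0.25 to 0.93 and ZNF468 from 0.09 to 1.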

Other observations

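Several tests here were chosen only after the result was seen, namely those of replicate number, of the sample labels and their exchange, of the intron-keeping ALKBH5 transcript and of the other splits, while those of GC content, depth and RPL21 were written before. The replicate number is a label given in the titles, not a condition, and libraries were not grouped by their ALKBH5 level. Between the libraries numbered 2 and 1 (n = 3 each, 1 of each group), interferon-stimulated genes were higher in number 2. In the fit with group and replicate number, edgeR called 28 of 30 higher and 1 lower, with a median log2 fold change of 0.97. Over all 14497 tested genes it called 3303 higher and 3282 lower, and the list counts here are to be read against these. OAS3, an antiviral oligoadenylate synthetase, was at 541 ± 27.5 against 119 ± 8.89 CPM (SD), a log2 fold change of 2.18 (SE 0.09, edgeR adjusted p = 1.4e-06). IFIT2 was at 2.37 (SE 0.11) and the chemokine gene CXCL10 at 2.32 (SE 0.14). Proliferation genes were higher too, with 17 of 22 G2/M genes called higher and 0 lower, among them TOP2A, a DNA topoisomerase gene, at 1.57 (SE 0.13) and MKI67, a proliferation marker, at 0.85 (SE 0.09). Of 15 homologous recombination and Fanconi genes 10 were higher and 1 lower, and of 25 G1/S genes 14 were higher and 2 lower. Of 21 genes of the integrated stress response 15 were higher and 2 lower, the higher ones including CHAC1 at 1.82 (SE 0.13) and SESN2, a sestrin gene, at 1.79 (SE 0.12). SLC7A5, an amino acid transporter gene, was lower at -1.14 (SE 0.08).

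Genes of ribosome production were lower in the libraries numbered 2. All but 1 of 23 MYC and nucleolar genes were called lower (22), among them SRM, spermidine synthase, at -1.10 (SE 0.09) and NOP2, a nucleolar RNA methyltransferase gene, at -1.14 (SE 0.09), and MYC itself was at -0.59 (SE 0.09). Of 75 ribosomal protein genes 54 were lower and 1 higher, and of 36 nuclear oxidative phosphorylation genes 22 were lower. Of 20 oxidative stress and NRF2 genes 14 were lower and 2 higher, with NQO1 at -1.61 (SE 0.09) and HMOX1, haem oxygenase, at -1.12 (SE 0.09). Of 16 integrin and adhesion genes 9 were lower, such as SELPLG, the ligand of P-selectin, at -1.39 (SE 0.10). Of 28 immediate-early genes 11 were lower and 1 higher, of 13 heat shock genes 6 were lower, and of 25 translation factor genes 10 were lower and 1 higher. The share called in these 3 lists was near that of all tested genes (6585 of 14497), though the calls were mostly lower. camera called these 13 lists, 5 higher and 8 lower, with adjusted p from 3.2e-11 for interferon-stimulated genes to 0.0416 for heat shock genes. None held with an estimated correlation (adjusted p = 0.562 to 0.837), and fry called 9 of the 38 lists. Monocyte markers went both ways, 7 higher and 7 lower, with CD14 at -0.72 (SE 0.08). Of the genes named by size, SPP1 was at -3.13 (SE 0.11), CAV1, a component of caveolae, at -3.19 (SE 0.22), CTTN, an actin regulator, at -2.98 (SE 0.14), FADS2, a fatty acid desaturase gene, at 2.22 (SE 0.08) and RNASE6 at 2.49 (SE 0.20). HIST2H2AA3 was at -3.22 (SE 0.57) and has an identical copy, so its counts are uncertain, and DESeq2 did not call it. AXL was at 1.33 (SE 0.32, edgeR adjusted p = 0.0076), TYRO3 at 1.10 (SE 0.12), PROS1 at 0.94 (SE 0.12) and GAS6 at -0.72 (SE 0.08).

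Between the 2 libraries of every group ALKBH5 differed by at least 6.16 on the log2 scale, and between same-numbered libraries by at most 0.24, which raised the question of wrong labels and does not decide it, since any difference tied to the number gives these values. An exchange of labels among these 6 libraries alone would not repair this, since 0 of the 15 ways to pair them leaves ALKBH5 alike within all 3 groups. With offsets for GC content and transcript length 93.8% of the called genes were still called in the same direction, and after thinning to the smallest total 93.3%, which argues against either as the whole cause. The split by number gave 7276 genes without a group term and the other 9 splits at most 0, but 10 splits are too few for a share under 0.05. Open stay labels wrong in some other way and libraries from outside these groups, while no label names a batch, and neither a batch nor a biological explanation was tested.

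The ALKBH5 transcript that keeps an intron did not follow the main transcript. It was estimated at 6.9, 18.5 and 34.8 counts in the libraries labelled shCtrl, shALKBH5 and ALKBH5 rescue replicate 1 (3.64%, 9.32% and 12.6% of the main transcript), and at 2.8, 1.4 and 1.4 counts in those numbered 2 (at most 0.0136%). An intron-free copy of the gene as the source of the high signal was considered and stays undecided. The percentage falls largely because the main transcript is higher, and an added copy alone would leave the counts of the intron-keeping transcript as they were. Their lower values in number 2 are unexplained, and how the estimates divide shared reads was not examined.

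The single gene called between labelled groups, RPL21P16, was weighed against reads shared with RPL21. The sum of both genes was 0.74 higher on the log2 scale in shALKBH5 than in shCtrl (SE 0.30, with the block), neither near 0 nor clearly above 0.5. RPL21P16 made up 275 of the 6628 summed counts in the library labelled shALKBH5 replicate 2. The sum thus follows RPL21, which alone was 0.71 higher (SE 0.29), and cannot decide on sharing, which stays open. RPL21 itself was at 132 CPM in the library labelled shCtrl replicate 2 and at 333 and 402 CPM in those labelled shALKBH5 and ALKBH5 rescue replicate 2, and other copies of RPL21 were not examined.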
